A study of Homo sapiens with 6 samples.

How the data were processed

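Total RNA depleted of ribosomal RNA was measured in 6 libraries of HepG2 cells, 3 kept in 0.1 nM insulin (sensitive) and 3 in 3 nM insulin (resistant) for 3 days, followed by 4 h without insulin. Per the labels, the libraries were sequenced as 150-base pairs of reads with at least 200 M reads planned for each. The labels do not say whether the replicates were separate cultures, so the p-values measure only the spread between these samples. The labels mention spike-ins, and the count tables hold no spike-in entries.

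The authors mapped the reads to GRCh38 with STAR 2.7.1a, allowing up to 100 alignments and 200 anchor loci per read, and counted them per gene and per repeat subfamily with TEcount of TEtranscripts 2.2.3 in its mode for reads with many alignments. The deposited tables give these values as counts, 1 table per library. The repeat annotation is named by the authors with the mouse build GRCm38, while the repeat names in the tables are those of human elements such as L1HS and SVA_F. The strand used in counting is not stated, so reads of overlapping genes on opposite strands may not have been told apart. The authors' deposited comparison table gives a log2 ratio of resistant over sensitive (log2), a p-value and adjusted p-value, and a mean normalised signal per entry. Its calls were compared with those made here. A deposited table of rlog values from DESeq2 1.42.1 was left out because the counts of the same libraries were tested.

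The tables hold 60448 genes and 1181 repeat subfamilies, and 15918 of these 61629 entries had no count in any library. Gene symbols, positions, exon lengths and GC content came from GENCODE release 44, which covers 56434 of the genes, and 9 further genes were named from the authors' table. The total was 145.3 to 185.3 M counts per library, and repeats took 18.6 to 37.2 M of them. The common biological coefficient of variation was 12.5%. The chi-square per degree of freedom between replicates, over entries with at least 20 counts, was 25.6 to 163, so within each group no library duplicated another. Intervals of shares are Wilson intervals at 95% and cover counting error only.

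Genes and repeats were tested together in edgeR 4.0.16 (R 4.3.3) with TMM factors, which ranged from 0.978 to 1.043, the filterByExpr filter, a quasi-likelihood fit with the group as the only term, a two-sided test and Benjamini-Hochberg adjustment over 30374 entries, at a threshold of 0.05. Log2 fold changes are given as resistant over sensitive with the standard error (SE), and levels as CPM, read counts scaled to a common library size by the TMM factors, with the standard deviation (SD). Gene lists and repeat families with at least 4 tested members were tested two-sided with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 34 lists or the 34 families, and again with an estimated correlation and with fry. The repeat share of counts was compared by an exact two-sided permutation test, which for 3 against 3 cannot go below 0.1. Library size factors scale each library to the others, so a change common to all genes could not be seen.

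The 34 gene lists were fixed before the data were examined, as were the first set of alternative settings and the rule for naming genes. The lists were lipogenesis, cholesterol synthesis and uptake, gluconeogenesis, FOXO targets, insulin signalling components, immediate early and MAPK feedback genes, NRF2 targets, antioxidant enzymes, the integrated stress response, ER chaperones and unfolded protein response, the heat shock response, hepatocyte markers, acute phase proteins, NF-kB and inflammatory genes, interferon-stimulated genes, heterochromatin factors, the cell cycle, glycolysis, the hypoxia response, fatty acid oxidation and PPARA targets, bile acid and xenobiotic metabolism, p53 targets, ribosome biogenesis, mitochondrially encoded genes, nuclear respiratory chain genes, cytosolic ribosomal proteins, replication-dependent histones, ZNF-named zinc finger genes, nuclear long noncoding RNAs, abundant small structural RNAs, and markers of fibroblasts, endothelial cells, immune cells, and cholangiocytes and progenitors.

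Genes were named by 4 rules. The first took up to 10 genes per direction with the largest log2 fold change among those past the test with a mean of at least 1 CPM, a symbol and group ranges that did not overlap. The second took up to 4 members of each list with the smallest adjusted p. The third took 13 genes whatever their value, among them INSR, IRS1, IGFBP1, G6PC1, FASN, CBX5 and FBL. The last took up to 5 repeat subfamilies per direction with the smallest adjusted p and 10 fixed subfamilies, of which 9 were in the tables. HSATII was not.

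The procedure was tested on simulated data with the means and dispersions of these libraries and 200 changed genes. It recovered 53 of 67 genes changed 1.5-fold (79.1%), 66 of 67 changed 2-fold (98.5%) and 66 of 66 changed 4-fold, with 15 false calls among 200. A list shifted by 0.3 on the log2 scale was recovered in its direction, and 0 other lists were called. The 200 changed genes were drawn from those with a mean of at least 1 CPM outside the gene lists. Recovery at lower levels was therefore not measured. All genes were simulated independently of each other, without a GC trend or a difference in repeat share between libraries. The simulation therefore does not measure how often lists are called falsely in these data.

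The alternative settings fixed at that point were DESeq2 1.42.0 with its own size factors, edgeR with RLE factors, factors from genes alone, mitochondrial, ribosomal and small structural RNAs left out, no filter, a filter of at least 1 CPM in 3 libraries, limma-voom, a replicate block, and leaving out each library in turn. After the data had been seen, a correction for a smooth trend over GC content and exon length in each library (loess span 0.3, 28137 genes with a known GC content) and the repeat share as a covariate were added.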

Results

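Total RNA depleted of ribosomal RNA was sequenced from HepG2, a line derived from a human hepatocellular carcinoma. The cells had been kept for 3 days in 0.1 nM insulin, the sensitive group (n = 3), or in 3 nM insulin, the resistant group (n = 3), and then for 4 h without insulin. The sensitive libraries held 181.2, 145.3 and 168.7 M counts over genes and repeat subfamilies, and the resistant libraries held 152.6, 157.7 and 185.3 M. The comparison asks how prolonged high insulin altered transcription and the silencing of heterochromatin. Corrections for GC content and exon length and for the share of counts on repeats, and the gene counts by GC content, were chosen after the data had been seen.

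Prolonged exposure to 3 nM insulin went with a lower level of the insulin receptor and of ERBB3, and with a higher level of the nuclear RNAs MALAT1 and NEAT1 and of the stress response genes ASNS, STC2 and DDIT4. Of 17 integrated stress response genes tested, 5 rose and 2 fell, with a median log2 fold change of 0.05. Their call by camera was lost without sensitive replicate 3 (adjusted p = 0.248). The lists of histones, hepatocyte markers and gluconeogenesis were called lower by camera at a preset correlation between genes (adjusted p = 4.12e-16, 1.09e-05 and 0.000111), and for each the adjusted p = 0.745 with an estimated correlation. MALAT1 (ENSG00000251562; GRCh38, chromosome 11, 65497640 to 65508073), a long RNA retained in nuclear speckles, went from 1300.1 ± 522 to 3559 ± 251 CPM, read counts scaled to a common library size (SD, n = 3 each). In sensitive replicates 1, 2 and 3 MALAT1 had 865.4, 1156.4 and 1878.5 CPM. Among 30374 genes and repeat subfamilies tested, 29213 were genes, of which 2059 rose and 3093 fell by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Changes over 1.5-fold numbered 1048 upward and 844 downward, and changes over 2-fold numbered 425 and 187. The median log2 fold change of all genes was -0.01. The groups' ranges did not overlap in 10801 genes, where chance gives 10% on average, but genes are not independent replicates.

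The number of genes called depended on the libraries. It was 2216 without sensitive replicate 1, 1668 without sensitive replicate 2, 9025 without sensitive replicate 3, 2732 without resistant replicate 1 and 869 without resistant replicate 3, and with GC content and exon length corrected it was 1631, with 821 higher and 810 lower. In every list called lower the number of members that fell was smallest without resistant replicate 3. Sensitive replicate 3 stood apart from its group: repeats took 17.5% of its counts against 11.3% and 12.8% in sensitive replicates 1 and 2, and mitochondrially encoded genes took 3.95% against 5.77% and 5.81%. The 95% Wilson intervals of these shares were at most 0.0121 points wide and cover counting error only. GC content moved with the groups as well. Of the 3715 protein-coding genes with the lowest GC content (up to 41.9%), 780 rose and 61 fell, and of the 3712 with the highest (from 56.7%), 19 rose and 1487 fell.

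The largest rises among genes with at least 1 CPM began with SLC6A14 (ENSG00000268104; chromosome X, 116436606 to 116461458), a broad amino acid transporter, which went from 4.84 ± 0.237 to 16.9 ± 5.65 CPM (SD, n = 3 each; log2 fold change 1.81 ± 0.19 SE, edgeR adjusted p = 0.00149). ANGPTL8, a secreted regulator of lipoprotein lipase, had a log2 fold change of 1.62 ± 0.30 (edgeR adjusted p = 0.00672). MALAT1 had a log2 fold change of 1.45 ± 0.23 (edgeR adjusted p = 0.00415). SEMA3A, a secreted guidance cue, rose by 1.44 and LSAMP, a cell surface adhesion protein, by 1.41 on the log2 scale. INHBE, which encodes the activin beta E subunit and is a liver-secreted factor, went from 3.2 ± 0.42 to 8.46 ± 2.56 CPM. The other large rises were the long noncoding RNA LINC02334 (1.47), ZNF341 (1.43; edgeR adjusted p = 0.0149, but 0.0582 without sensitive replicate 2, 0.0645 without resistant replicate 1 and 0.0629 without resistant replicate 3), and the pseudogenes FYTTD1P1 (1.58) and RNY4P34 (1.38), which share sequence with their parent genes. ZNF341 had 3.00 CPM in resistant replicate 2, close to the 2.95 of sensitive replicate 1, and 10.8 and 7.91 in resistant replicates 1 and 3.

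The largest falls by estimate were in PCDH1, a protocadherin, from 1.69 ± 0.2 to 0.413 ± 0.205 CPM (SD, n = 3 each; log2 fold change -2.02 ± 0.28 SE, edgeR adjusted p = 0.0039), and in MT-RNR1, the mitochondrial 12S ribosomal RNA. MT-RNR1 is a target of ribosomal RNA depletion, and its level in the sensitive libraries was uneven, at 5.38, 13.4 and 31.7 CPM. Its log2 fold change of -2.02 shrank to -1.17 without sensitive replicate 3 (edgeR adjusted p = 0.00635). Its edgeR adjusted p of 0.0126 became 0.0617 without resistant replicate 3. ACSM3 (ENSG00000005187; chromosome 16, 20610243 to 20797581), a mitochondrial medium-chain acyl-CoA synthetase, fell from 277 ± 26.8 to 111 ± 2.78 CPM (log2 fold change -1.32 ± 0.09 SE, edgeR adjusted p = 0.000328). RASSF5, a Ras effector, fell by 1.46 on the log2 scale, GDPD5, a glycerophosphodiesterase, by 1.30, and GALNT16, a glycosyltransferase, by 1.46. NYNRIN (log2 fold change -1.30) and ATP6V1B1 (-1.29), a proton pump subunit, fell too. FSTL4 (-1.63; edgeR adjusted p = 0.00929, but 0.0565 without resistant replicate 3) and RASA4 (-1.41; 0.0141, but 0.0537 without sensitive replicate 2) completed the set, and RASA4 has a close paralog. The log2 fold change of FSTL4 was -2.29 without resistant replicate 2 (edgeR adjusted p = 0.00269).

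**Figure D1:**
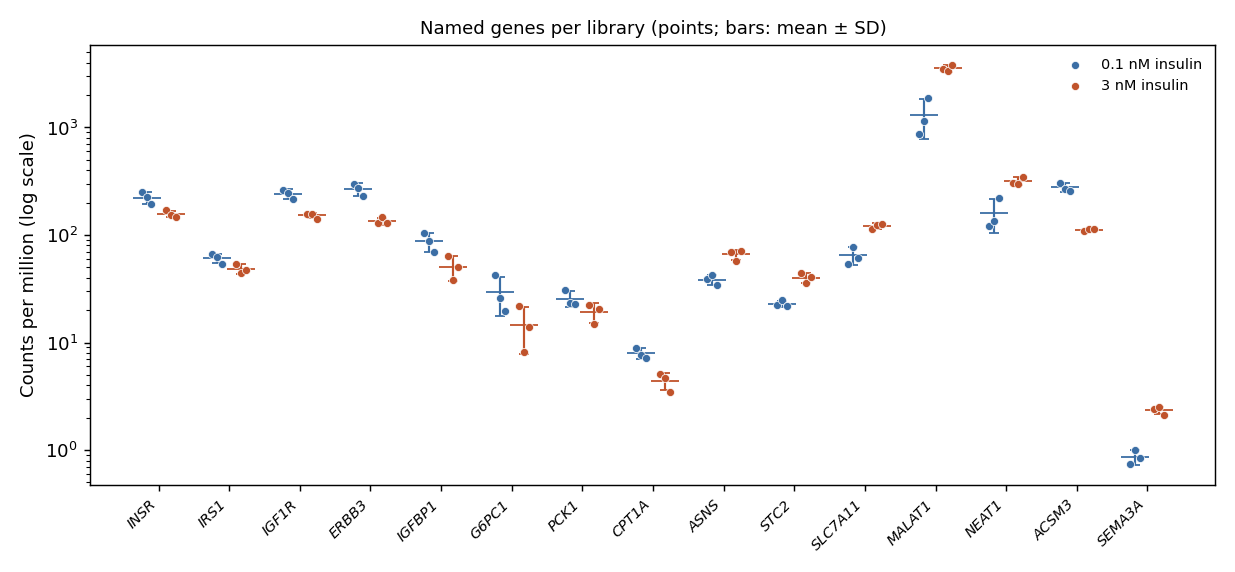
CPM (vertical axis, log scale) of 15 genes in each library, with points for the 3 libraries of 0.1 nM insulin (blue) and the 3 of 3 nM insulin (orange) and bars for the mean ± SD. MALAT1 rose from a mean of 1300.1 to 3559 CPM and ACSM3 fell from 277 to 111 CPM.

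The insulin receptor was lower after 3 nM insulin. INSR (ENSG00000171105; chromosome 19, 7112255 to 7294414) went from 222 ± 27.4 to 157 ± 10.9 CPM (SD, n = 3 each; log2 fold change -0.50 ± 0.10 SE, edgeR adjusted p = 0.00928). IGF1R, the receptor of insulin-like growth factor 1, fell from 242 ± 25.2 to 152 ± 8.29 CPM, and ERBB3, a receptor tyrosine kinase, from 267 ± 35.7 to 135 ± 9.82. IRS1, an adaptor of the receptor, fell by 0.33 on the log2 scale (edgeR adjusted p = 0.0414). IRS2 had a log2 fold change of -0.67 ± 0.42 SE and did not pass the test (edgeR adjusted p = 0.282). The INSR adjusted p was 0.0654 without resistant replicate 3, and that of IRS1 was 0.142 without sensitive replicate 1, 0.136 without sensitive replicate 2, 0.0874 without resistant replicate 2 and 0.155 without resistant replicate 3. Among insulin signalling components, of 30 tested genes 3 rose and 9 fell (3 and 10 adjusted over the list alone, 0 to 3 rose and 1 to 11 fell leaving out 1 library). Their median log2 fold change was -0.13 (camera adjusted p = 0.0212, and adjusted p = 0.745 with an estimated correlation). The members that rose included GRB14, an inhibitor of the receptor (0.48; edgeR adjusted p 0.0617 without resistant replicate 3), and the phosphatidylinositol 3-kinase subunit PIK3R2 was among those that fell (-0.51; edgeR adjusted p 0.0531 without resistant replicate 3). The list's camera adjusted p was 0.0626 without sensitive replicate 2, 0.237 over genes of at least 1 CPM in 3 libraries, and 0.073 with GC content and length corrected.

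Genes activated by FOXO transcription factors, which insulin signalling holds out of the nucleus, were tested as a list. For FOXO targets, of 20 tested genes 1 rose and 7 fell (2 and 9 adjusted over the list alone, 0 to 2 rose and 2 to 12 fell leaving out 1 library). The FOXO list's median log2 fold change was -0.24 (camera adjusted p = 0.00107, and adjusted p = 0.745 with an estimated correlation). ERBB3 and TNFSF10, the death ligand TRAIL, led the list at log2 fold changes of -0.99 ± 0.11 and -0.98 ± 0.11 SE. IGFBP1, a secreted binding protein of insulin-like growth factors, went from 87.2 ± 17.1 to 50.8 ± 13.2 CPM (SD, n = 3 each; edgeR adjusted p = 0.0135, but 0.0528 without sensitive replicate 2 and 0.0644 without resistant replicate 3). After correction for GC content and length, 1 rose and 7 fell. The list was still called lower by camera (adjusted p = 2.16e-05, and 0.684 with an estimated correlation).

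Gluconeogenesis was called lower: of 16 tested genes 0 rose and 8 fell (0 and 12 adjusted over the list alone, 0 rose and 1 to 11 fell leaving out 1 library). The gluconeogenesis list's median log2 fold change was -0.37 (camera adjusted p = 0.000111, and adjusted p = 0.745 with an estimated correlation). Pyruvate carboxylase, PC, fell by 0.52 on the log2 scale (edgeR adjusted p = 0.00439). G6PC1, the catalytic subunit of glucose-6-phosphatase, went from 29.3 ± 11.6 to 14.7 ± 6.9 CPM (SD, n = 3 each; edgeR adjusted p = 0.0474). This call was lost with DESeq2 (adjusted p = 0.143), factors from genes alone (0.0541), structural RNAs left out (0.0512) and a filter of 1 CPM in 3 libraries (0.0773). In leave-one-out fits the edgeR adjusted p was 0.173 without sensitive replicate 1, 0.0925 without sensitive replicate 2, 0.111 without resistant replicate 2 and 0.145 without resistant replicate 3. PCK1, which makes phosphoenolpyruvate from oxaloacetate, had 25.6 ± 4.28 CPM after 0.1 nM and 19.3 ± 4.05 CPM after 3 nM insulin (edgeR adjusted p = 0.0829). PCK1 was called lower with DESeq2 (adjusted p = 0.0373), no filter (0.0151), the replicate block (0.00658) and without sensitive replicate 3 (0.0348). The glucose-6-phosphate transporter SLC37A4 had a log2 fold change of -0.59 (edgeR adjusted p = 0.00745, but 0.0532 without resistant replicate 3). When GC content and length were corrected, 0 rose and 1 fell. Camera still called the list lower with that correction (adjusted p = 0.000165, and 0.511 with an estimated correlation).

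In fatty acid oxidation and PPARA targets, of 16 tested genes 1 rose and 4 fell (1 and 8 adjusted over the list alone, 0 to 1 rose and 1 to 8 fell leaving out 1 library). In that list the median log2 fold change was -0.20 (camera adjusted p = 0.0458, and adjusted p = 0.745 with an estimated correlation). CPT1A, which passes long-chain fatty acids into mitochondria, fell from 7.92 ± 0.896 to 4.42 ± 0.834 CPM (SD, n = 3 each; edgeR adjusted p = 0.00525). That list's camera adjusted p was 0.176 without sensitive replicate 1, 0.272 without resistant replicate 2, 0.0784 without resistant replicate 3 and 0.354 over genes of at least 1 CPM in 3 libraries. With GC content and length corrected it was 0.0193, and 0.684 with an estimated correlation. In lipogenesis, 1 rose and 2 fell of 18 (1 and 2 adjusted over the list alone, 0 to 1 rose and 0 to 4 fell leaving out 1 library, median -0.05, camera adjusted p = 0.406). FASN, fatty acid synthase, had a log2 fold change of -0.12 ± 0.11 SE and SREBF1, the transcription factor that drives it, -0.02 ± 0.09 SE, and neither passed the edgeR test (adjusted p = 0.491 and 0.879). Both turned positive after correction for GC content and length, at 0.27 and 0.34, where SREBF1 passed as higher (edgeR adjusted p = 0.0248) and FASN did not (0.108), and SREBF1 was also positive over genes of at least 1 CPM in 3 libraries (0.023). In cholesterol synthesis and uptake, 1 rose and 4 fell of 23 (4 and 5 adjusted over the list alone, 1 to 2 rose and 0 to 7 fell leaving out 1 library, median -0.06, camera adjusted p = 0.575). STARD4, a cholesterol carrier, rose by 0.48 on the log2 scale. In glycolysis, 1 rose and 2 fell of 21 (1 and 2 adjusted over the list alone, 0 to 1 rose and 1 to 5 fell leaving out 1 library, median -0.10, camera adjusted p = 0.345). PFKL, the liver phosphofructokinase, had a log2 fold change of -0.62.

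Among hepatocyte markers, of 25 tested genes 1 rose and 13 fell (1 and 14 adjusted over the list alone, 0 to 1 rose and 3 to 16 fell leaving out 1 library). The markers' median log2 fold change was -0.41 (camera adjusted p = 1.09e-05, and adjusted p = 0.745 with an estimated correlation). APOE, an apolipoprotein, fell from 267 ± 18.3 to 163 ± 6.97 CPM (SD, n = 3 each, edgeR adjusted p = 0.00304). Its log2 fold change went from -0.71 to -0.27 with GC content and length corrected (edgeR adjusted p = 0.0426). The liver transcription factor CEBPA fell by 0.78 on the log2 scale. After that correction for GC content and length, 0 rose and 5 fell among these markers. Camera still called them lower (adjusted p = 1.48e-05, and 0.684 with an estimated correlation). In acute phase proteins, 2 rose and 4 fell of 13 (3 and 5 adjusted over the list alone, 1 to 2 rose and 2 to 6 fell leaving out 1 library, median -0.13, camera adjusted p = 0.166). SOCS3, the feedback inhibitor of cytokine signalling, went from 0.78 ± 0.162 to 0.195 ± 0.0357 CPM (SD, n = 3 each; edgeR adjusted p = 0.00301), haptoglobin (HP) fell by 0.65 on the log2 scale, and SERPINA3 rose by 0.68. In bile acid and xenobiotic metabolism, 1 rose and 3 fell of 18 (1 and 4 adjusted over the list alone, 0 to 2 rose and 1 to 5 fell leaving out 1 library, median -0.17, camera adjusted p = 0.184), with the oxygenase CYP1A1 lower (log2 fold change -0.64).

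Antioxidant enzymes were called lower: of 23 tested genes 1 rose and 9 fell (2 and 11 adjusted over the list alone, 0 to 1 rose and 1 to 11 fell leaving out 1 library). The enzymes' median log2 fold change was -0.25 (camera adjusted p = 0.0046, and adjusted p = 0.745 with an estimated correlation). The list's camera adjusted p was 0.0966 over genes of at least 1 CPM in 3 libraries. GSTA1, a glutathione transferase, fell by 1.08 on the log2 scale (edgeR adjusted p = 0.0075). In NRF2 targets, 1 rose and 7 fell of 20 (1 and 8 adjusted over the list alone, 1 to 2 rose and 1 to 10 fell leaving out 1 library, median -0.15, camera adjusted p = 0.0606). Camera called that list lower without sensitive replicate 1 (adjusted p = 0.0257), without resistant replicate 2 (0.00579) and with the replicate block (0.0412), where with an estimated correlation the adjusted p = 0.755, 0.765 and 0.734. SLC7A11, the cystine importer, rose from 64.5 ± 12.2 to 122 ± 7.74 CPM (SD, n = 3 each; edgeR adjusted p = 0.0039), while the aldo-keto reductase AKR1C2, which shares sequence with its paralogs, fell by 0.61 on the log2 scale. Among the antioxidant enzymes, 0 rose and 3 fell after correction for GC content and length. Camera still called these enzymes lower (adjusted p = 0.0193, and 0.684 with an estimated correlation).

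In the integrated stress response, of 17 tested genes 5 rose and 2 fell (5 and 2 adjusted over the list alone, 3 to 5 rose and 0 to 3 fell leaving out 1 library). The stress genes' median log2 fold change was 0.05 (camera adjusted p = 0.0395, and adjusted p = 0.745 with an estimated correlation). ASNS, asparagine synthetase, rose from 38.4 ± 4.02 to 66.1 ± 7.19 CPM (SD, n = 3 each; log2 fold change 0.78 ± 0.10 SE, edgeR adjusted p = 0.0039). STC2, a secreted glycoprotein, rose from 22.9 ± 1.55 to 40.1 ± 4.23 and DDIT4, an inhibitor of mTORC1, from 5.25 ± 0.321 to 8.87 ± 1.1 CPM. ATF5 fell by 0.65 on the log2 scale (edgeR adjusted p = 0.0136, but 0.0625 without sensitive replicate 2 and 0.0734 without resistant replicate 3). For ER chaperones and the unfolded protein response, of 18 tested genes 2 rose and 0 fell (2 and 0 adjusted over the list alone, 0 to 2 rose and 0 to 1 fell leaving out 1 library). The chaperone list's median log2 fold change was 0.12 (camera adjusted p = 0.0458, and adjusted p = 0.745 with an estimated correlation). HSP90B1, an ER chaperone, went from 1044 ± 88.1 to 1374 ± 29.6 CPM (edgeR adjusted p = 0.0213, but 0.0702 without sensitive replicate 1, 0.0581 without sensitive replicate 2, 0.08 without resistant replicate 1, 0.0599 without resistant replicate 2 and 0.0886 without resistant replicate 3). Both calls rested on single libraries: the camera adjusted p of the integrated stress response was 0.248 without sensitive replicate 3 and 0.0684 without resistant replicate 1, and that of the ER chaperones 0.242 without sensitive replicate 3, 0.11 without resistant replicate 1 and 0.0808 without resistant replicate 2. In the integrated stress response, 8 rose and 0 fell with GC content and length corrected. Camera then called this list and the ER chaperones higher (adjusted p = 1.87e-09 and 0.00236, and 0.511 and 0.684 with an estimated correlation).

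In the heat shock response, 3 rose and 2 fell of 15 (3 and 3 adjusted over the list alone, 1 to 4 rose and 1 to 5 fell leaving out 1 library, median -0.01, camera adjusted p = 0.964). The small heat shock protein HSPB1 fell by 0.66 on the log2 scale and the HSP90 cochaperone CHORDC1 rose by 0.48. Among p53 targets, 5 rose and 0 fell of 16 (5 and 0 adjusted over the list alone, 0 to 5 rose and 0 fell leaving out 1 library, median 0.07, camera adjusted p = 0.0857). Camera called this list higher with GC content and length corrected (adjusted p = 0.000317, median 0.23), with the repeat share as a covariate (0.00843), without resistant replicate 2 (0.00196) and without sensitive replicate 1 (0.0261), where with an estimated correlation the adjusted p = 0.684, 0.698, 0.765 and 0.755. RRM2B, a ribonucleotide reductase subunit, was among the p53 targets that rose (log2 fold change 0.56, edgeR adjusted p = 0.0138, but 0.056 without sensitive replicate 2 and 0.0584 without resistant replicate 3). In the hypoxia response, 2 rose and 2 fell of 15 (2 and 2 adjusted over the list alone, 1 to 2 rose and 1 to 2 fell leaving out 1 library, median -0.0032, camera adjusted p = 0.911), and camera leaned upward although the median and mean were negative. NDRG1, a stress-induced gene, fell by 0.87 on the log2 scale, and PDK1, which inhibits pyruvate dehydrogenase, rose by 0.56. In NF-kB and inflammatory genes, 1 rose and 0 fell of 15 (1 and 0 adjusted over the list alone, 0 to 2 rose and 0 to 2 fell leaving out 1 library, median 0.09, camera adjusted p = 0.536). For interferon-stimulated genes, 1 rose and 0 fell of 22 (1 and 0 adjusted over the list alone, 0 to 2 rose and 0 to 1 fell leaving out 1 library, median -0.03, camera adjusted p = 0.911), and the mean and camera were upward while the median was negative.

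Among replication-dependent histones, of 58 tested genes 0 rose and 34 fell (0 and 49 adjusted over the list alone, 0 rose and 6 to 50 fell leaving out 1 library). The histones' median log2 fold change was -0.41 (camera adjusted p = 4.12e-16, and adjusted p = 0.745 with an estimated correlation). H4C5 fell from 169 ± 9.84 to 107 ± 20.1 CPM and H3C4 from 54.2 ± 2.96 to 35.8 ± 4.15 (SD, n = 3 each; edgeR adjusted p = 0.00681 and 0.0046). Histone genes are close copies of each other, so reads of single members are uncertain. In the cell cycle list, of 25 tested genes 0 rose and 9 fell (0 and 11 adjusted over the list alone, 0 rose and 0 to 16 fell leaving out 1 library). In the cycle list the median log2 fold change was -0.30 (camera adjusted p = 6.86e-05, and adjusted p = 0.745 with an estimated correlation). MCM5, a subunit of the replicative helicase, fell by 0.71 on the log2 scale (edgeR adjusted p = 0.0149, but 0.061 without sensitive replicate 2 and 0.0739 without resistant replicate 3). Among the histones 0 rose and 7 fell after correction for GC content and length, and in the cell cycle list 0 rose and 2 fell. Both were still called lower by camera (adjusted p = 1.02e-12 and 7.64e-06, and 0.684 for each with an estimated correlation). For immediate early and MAPK feedback genes, of 24 tested genes 1 rose and 7 fell (1 and 7 adjusted over the list alone, 0 to 1 rose and 1 to 7 fell leaving out 1 library). For these early genes the median log2 fold change was -0.16 (camera adjusted p = 0.0446, and adjusted p = 0.745 with an estimated correlation). ETV4, a transcription factor downstream of MAPK, fell by 0.59 on the log2 scale. The camera adjusted p of that list was 0.239 without sensitive replicate 1, 0.0934 without sensitive replicate 2, 0.0697 without resistant replicate 2, 0.237 over genes of at least 1 CPM in 3 libraries and 0.418 with GC content and length corrected.

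Cytosolic ribosomal protein genes were called lower: of 80 tested genes 2 rose and 17 fell (2 and 19 adjusted over the list alone, 0 to 2 rose and 0 to 36 fell leaving out 1 library). The ribosomal list's median log2 fold change was -0.16 (camera adjusted p = 1.07e-05, and adjusted p = 0.745 with an estimated correlation). RPL13 went from 738 ± 33.8 to 540.4 ± 14.2 CPM (SD, n = 3 each; edgeR adjusted p = 0.0082, but 0.0621 without resistant replicate 3). Corrected for GC content and length, 0 rose and 4 fell. The list was still called lower by camera there (adjusted p = 8.61e-06, and 0.684 with an estimated correlation). In ribosome biogenesis, 1 rose and 4 fell of 20 (1 and 5 adjusted over the list alone, 0 to 3 rose and 0 to 6 fell leaving out 1 library, median -0.04, camera adjusted p = 0.375). FBL, fibrillarin, fell by 0.30 on the log2 scale (edgeR adjusted p = 0.0205, but 0.0724 without sensitive replicate 1, 0.0668 without sensitive replicate 2, 0.0577 without resistant replicate 1 and 0.11 without resistant replicate 3). NPM1, nucleophosmin, had a log2 fold change of 0.14 ± 0.10 SE (edgeR adjusted p = 0.361), which was -0.0285 with GC content and length corrected. The splicing factor SRSF2 (0.0018; edgeR adjusted p = 0.993) and the Mediator subunit MED1 (-0.06; edgeR adjusted p = 0.638) did not pass the test, and the sign of SRSF2 turned in some fits (-0.016 with no filter).

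The protein-coding genes of the mitochondrial genome, a list without MT-RNR1, were called although no member passed alone: of 13 tested genes 0 rose and 0 fell (0 and 0 adjusted over the list alone, 0 to 1 rose and 0 fell leaving out 1 library). The mitochondrial list's median log2 fold change was 0.28 (camera adjusted p = 0.0243, and adjusted p = 0.745 with an estimated correlation). By edgeR 0 of the 13 passed, 2 had an unadjusted p under 0.05, DESeq2 called 2, limma-voom 1 and the replicate block 6. MT-ND4L had a log2 fold change of 0.40 ± 0.14 SE (edgeR adjusted p = 0.0659). It was called higher with DESeq2 (adjusted p = 0.0246), limma-voom (0.0495), no filter (0.0145), a filter of 1 CPM in 3 libraries (0.0373), the replicate block (0.00619) and without sensitive replicate 3 (0.0393). The list's camera adjusted p was 0.556 without sensitive replicate 3, the library with the lowest mitochondrial share, 0.0764 without resistant replicate 2 and 0.136 with GC content and length corrected. In nuclear respiratory chain genes, 2 rose and 11 fell of 95 (2 and 11 adjusted over the list alone, 1 to 6 rose and 0 to 29 fell leaving out 1 library, median -0.07, camera adjusted p = 0.161). The respiratory chain list was called lower by camera without sensitive replicate 3 (adjusted p = 0.0204) and with GC content and length corrected (0.0283), where with an estimated correlation the adjusted p = 0.545 and 0.684. Its member with the smallest adjusted p, ATP5PBP1 (log2 fold change 1.05), is a pseudogene matched by its symbol.

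Nuclear long noncoding RNAs were called upward on few members: of 10 tested genes 3 rose and 0 fell (3 and 0 adjusted over the list alone, 2 to 3 rose and 0 to 1 fell leaving out 1 library). The noncoding list's median log2 fold change was 0.06 (camera adjusted p = 0.0395, and adjusted p = 0.745 with an estimated correlation). The list as fixed also took in NORAD, GAS5 and OIP5-AS1, and the place of its members in the cell was not measured. Its median therefore cannot stand for nuclear RNAs alone. Besides MALAT1, NEAT1, the scaffold of paraspeckles, rose from 159 ± 55.4 to 316 ± 26.8 CPM (SD, n = 3 each; edgeR adjusted p = 0.0072). In sensitive replicates 1, 2 and 3 NEAT1 had 120.15, 134.4 and 222.5 CPM. Within that group both RNAs rose in the same order as the repeat share. KCNQ1OT1 rose by 0.52 on the log2 scale (edgeR adjusted p = 0.0239, but 0.0675 without sensitive replicate 1, 0.0908 without sensitive replicate 2, 0.0503 without resistant replicate 1, 0.0848 without resistant replicate 2 and 0.106 without resistant replicate 3); it overlaps a coding gene, and the strand used in counting was not stated. That list's camera adjusted p was 0.0764 without resistant replicate 2 and 0.385 with GC content and length corrected. Abundant small structural RNAs were called lower: of 13 tested genes 0 rose and 6 fell (0 and 7 adjusted over the list alone, 0 rose and 2 to 7 fell leaving out 1 library). The structural RNAs' median log2 fold change was -0.34 (camera adjusted p = 1.59e-05, and adjusted p = 0.745 with an estimated correlation). With GC content and length corrected their camera adjusted p was 0.00255, and 0.684 with an estimated correlation. SCARNA2, a guide RNA of Cajal bodies, fell from 46.3 ± 2.12 to 26.8 ± 0.849 CPM, and RPPH1, the RNA of ribonuclease P, fell by 0.62 on the log2 scale (edgeR adjusted p = 0.00111 and 0.00501). The counts of SCARNA2 were identical to those of another annotated gene.

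With the repeat share of each library as a covariate, 556 genes were called and several list calls were lost: camera adjusted p was 0.386 for FOXO targets, 0.386 for antioxidant enzymes, 0.221 for hepatocyte markers and 0.188 for the cell cycle. It was 0.575 for insulin signalling components, 0.579 for immediate early genes, which then leaned upward, 0.91 for fatty acid oxidation and 0.102 for nuclear long noncoding RNAs. At the preset correlation camera still called histones, gluconeogenesis, ribosomal proteins, structural RNAs, the integrated stress response, ER chaperones and mitochondrially encoded genes, where with an estimated correlation the adjusted p = 0.696, 0.538, 0.726, 0.654, 0.538, 0.538 and 0.538. Fewer members passed: 0 of 58 histones fell (34 without the covariate, median -0.41 to -0.25), as did 1 of 16 gluconeogenesis genes (8, median -0.37 to -0.23), 3 of 80 ribosomal protein genes (17) and 2 of 13 structural RNAs (6). Camera calls were gained upward for cholesterol synthesis and uptake (6 rose and 0 fell of 23, adjusted p = 0.000492), p53 targets (0 rose and 0 fell, 0.00843) and the hypoxia response (2 rose and 1 fell, 0.0488), and with an estimated correlation the adjusted p = 0.538, 0.698 and 0.538. Of the 13 mitochondrially encoded genes 12 rose with this covariate, and their median log2 fold change went from 0.28 to 0.77. Calls of single named genes were not checked with this covariate, under which 389 of the 5152 genes called without it were still called. The correction for GC content and length kept 61 of the 128 calls of named genes to which it applied, among them those of INSR, ERBB3, IGF1R, TNFSF10, ACSM3, MALAT1, NEAT1, ASNS, STC2, DDIT4 and SLC7A11. It ended the edgeR calls of IRS1 (corrected log2 fold change -0.18, adjusted p = 0.207), PIK3R2 (-0.15, 0.252), G6PC1 (-0.94, 0.109), SLC37A4 (-0.34, 0.0565), PC (-0.23, 0.0569), STARD4 (0.23, 0.108), PFKL (-0.24, 0.0701) and CEBPA (-0.39, 0.0596). It also ended those of ATF5 (log2 fold change -0.36, edgeR adjusted p = 0.139), HSP90B1 (0.27, 0.0751), CHORDC1 (0.23, 0.0994), RRM2B (0.32, 0.162), MCM5 (-0.45, 0.124) and ETV4 (-0.29, 0.071). RPL13 (log2 fold change -0.22, edgeR adjusted p = 0.0838), FBL (-0.13, 0.231), KCNQ1OT1 (0.33, 0.0948), RPPH1 (-0.27, 0.105), RASA4 (-1.13, 0.0774), ATRX (0.29, 0.0665) and ZNF358 (-0.33, 0.0604) lost theirs too.

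**Figure D2:**
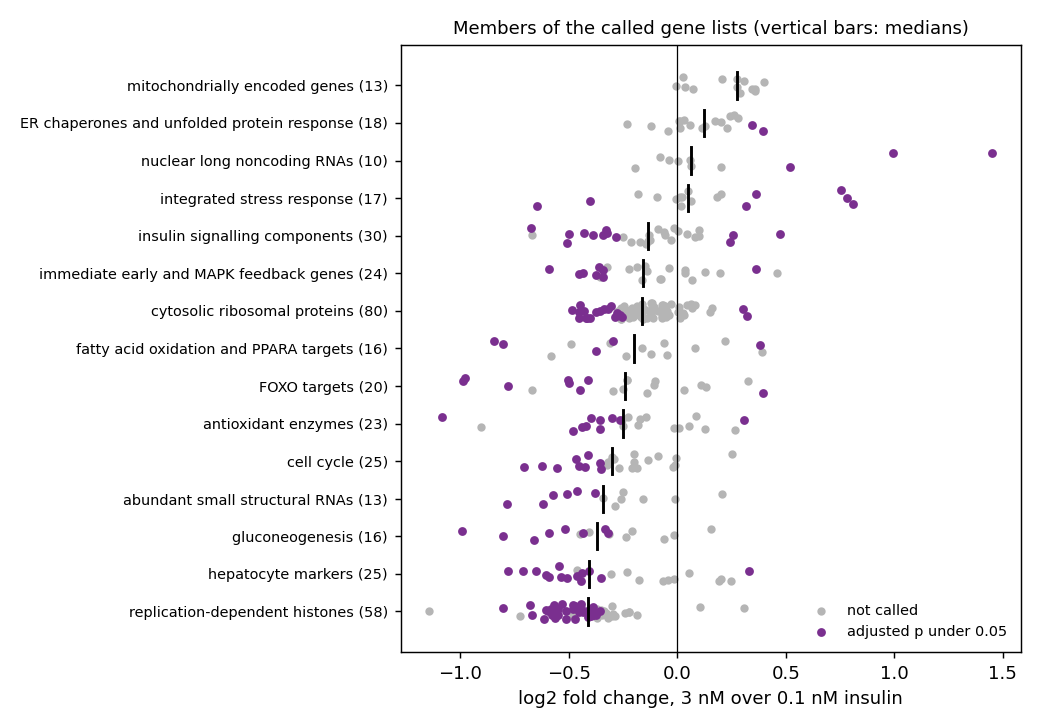
Log2 fold change of 3 nM over 0.1 nM insulin (horizontal axis) for the members of the 15 called gene lists, with purple points for members past the edgeR test, grey points for the others and black bars for the medians. Histones had the lowest median, -0.41, and mitochondrially encoded genes the highest, 0.28.

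Among heterochromatin factors, 3 rose and 7 fell of 26 (3 and 12 adjusted over the list alone, 0 to 3 rose and 1 to 13 fell leaving out 1 library, median -0.22, camera adjusted p = 0.0559). Camera called them lower with GC content and length corrected (adjusted p = 0.0393), with the replicate block (0.0373) and without resistant replicate 2 (0.000723), where with an estimated correlation the adjusted p = 0.684, 0.76 and 0.765. CBX5, the heterochromatin protein HP1 alpha, went from 206 ± 16 to 148 ± 23.1 CPM (SD, n = 3 each; edgeR adjusted p = 0.016, but 0.0735 without sensitive replicate 2, 0.0592 without resistant replicate 1 and 0.0944 without resistant replicate 3). TRIM28, the corepressor that zinc finger proteins recruit to repeats, fell from 173 ± 13.4 to 109.9 ± 19.5 CPM (edgeR adjusted p = 0.00634), and had a log2 fold change of -0.29 with GC content and length corrected (adjusted p = 0.122). ATRX, a chromatin remodeller, rose by 0.51 on the log2 scale (edgeR adjusted p = 0.00929, but 0.0536 without resistant replicate 3). Among ZNF-named zinc finger genes, 36 rose and 60 fell of 489 (37 and 61 adjusted over the list alone, 4 to 74 rose and 14 to 83 fell leaving out 1 library, median -0.02, camera adjusted p = 0.668). Camera called them lower with GC content and length corrected (adjusted p = 0.031, and adjusted p = 0.684 with an estimated correlation). ZNF358 and ZNF362 fell by 0.77 and 0.86 on the log2 scale and ZNF37A rose by 0.53.

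Markers of other cell types showed few calls. In fibroblast markers, 0 rose and 2 fell of 6 (1 and 3 adjusted over the list alone, 0 to 1 rose and 1 to 2 fell leaving out 1 library, median -0.11, camera adjusted p = 0.166). PDGFRB fell from 10.7 ± 1.24 to 5.71 ± 0.491 CPM (SD, n = 3 each; edgeR adjusted p = 0.00309). In immune cell markers, 0 rose and 1 fell of 7 (0 and 1 adjusted over the list alone, 0 rose and 0 to 3 fell leaving out 1 library, median -0.27, camera adjusted p = 0.208). LYZ, lysozyme, abundant in both groups, had 1608 ± 112 CPM after 0.1 nM and 1319.6 ± 49 CPM after 3 nM insulin (edgeR adjusted p = 0.0702). It was called lower with GC content and length corrected (log2 fold change -0.43, edgeR adjusted p = 0.0268), DESeq2 (0.0173), limma-voom (0.0341), no filter (0.0226), the replicate block (0.0269) and without sensitive replicate 3 (0.0078). In endothelial markers, 0 rose and 0 fell of 5 (0 and 0 adjusted over the list alone, 0 rose and 0 to 1 fell leaving out 1 library, median -0.49, camera adjusted p = 0.23). For cholangiocyte and progenitor markers, 0 rose and 0 fell of 8 (0 and 0 adjusted over the list alone, 0 rose and 0 to 1 fell leaving out 1 library, median 0.11, camera adjusted p = 0.911). In those last lists, where edgeR called 0, the unadjusted edgeR p was under 0.05 for 2 endothelial and 1 cholangiocyte gene, DESeq2 called 0 and 1, limma-voom 0 and 0, and the replicate block 1 and 2.

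The deposited differential expression table of the authors, made from the same libraries with TEtranscripts, listed 2208 genes higher and 3481 lower among 25777 with an adjusted p, and 860 repeat subfamilies higher and 3 lower among 1151. The edgeR calls shared 4949 genes and 706 repeat subfamilies with it, every shared one in the same direction.

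Repeat subfamilies, groups of related transposon or satellite copies counted together, were compared in the same fit to ask whether silenced elements were released. Nearly all calls were upward: of 1161 subfamilies tested, 708 rose and 3 fell, and 934 rose and 5 fell when adjusted over the repeats alone. The median log2 fold change was 0.52, and 360 rises exceeded 1.5-fold. The groups' ranges did not overlap in 779 subfamilies, where chance gives 10% on average. Subfamilies move together and are not independent replicates, so the excess over 10% is not a test. The call with the smallest adjusted p was Helitron1Nb_Mam, an old rolling-circle transposon, which went from 9.98 ± 1.56 to 20.9 ± 1.71 CPM (SD, n = 3 each; log2 fold change 1.07 ± 0.12 SE, edgeR adjusted p = 0.00177). The DNA transposons MER124, MER63C, MamRep434 and Charlie7a rose by 0.83, 0.75, 0.74 and 0.69 on the log2 scale.

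The 3 subfamilies that fell were FordPrefect, a DNA transposon, from 2958 ± 217 to 1531 ± 114 CPM (SD, n = 3 each; edgeR adjusted p = 0.00257), GSATII, a pericentromeric satellite, from 15 ± 0.783 to 10.7 ± 0.404, and 7SK, copies of the 7SK small nuclear RNA, from 154 ± 23.1 to 113 ± 6.73 (edgeR adjusted p = 0.0187, but 0.0648 without sensitive replicate 1, 0.0501 without resistant replicate 2 and 0.0872 without resistant replicate 3). The number of repeat subfamilies called was 388 without sensitive replicate 1, 262 without sensitive replicate 2, 1081 without sensitive replicate 3, 376 without resistant replicate 1, 471 without resistant replicate 2 and 189 without resistant replicate 3.

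L1HS, the human-specific LINE-1, went from 166 ± 44.5 to 239 ± 11.9 CPM (SD, n = 3 each; log2 fold change 0.53 ± 0.15 SE, edgeR adjusted p = 0.0336). L1PA2 rose by 0.57, the endogenous retroviruses HERVH-int and HERVK-int by 0.69 and 0.40, and LTR7, the promoter of HERVH, by 0.55 on the log2 scale (edgeR adjusted p = 0.0378, 0.0146, 0.0207 and 0.0314). None of these 5 calls held in all leave-one-out fits, and over entries of at least 1 CPM in 3 libraries the edgeR adjusted p was 0.0509 for L1HS, 0.0549 for L1PA2 and 0.0507 for LTR7. The edgeR adjusted p of L1HS was 0.0906 without sensitive replicate 1, 0.126 without sensitive replicate 2, 0.0885 without resistant replicate 1, 0.086 without resistant replicate 2 and 0.127 without resistant replicate 3. For L1PA2 it was 0.0969 without sensitive replicate 1, 0.137 without sensitive replicate 2, 0.103 without resistant replicate 1, 0.0893 without resistant replicate 2 and 0.135 without resistant replicate 3. It was 0.0715 without sensitive replicate 2, 0.0532 without resistant replicate 1 and 0.0714 without resistant replicate 3 for HERVH-int and 0.0674 without sensitive replicate 1, 0.0935 without sensitive replicate 2, 0.093 without resistant replicate 1 and 0.106 without resistant replicate 3 for HERVK-int. LTR7 had 0.0873 without sensitive replicate 1, 0.123 without sensitive replicate 2, 0.0937 without resistant replicate 1, 0.0735 without resistant replicate 2 and 0.118 without resistant replicate 3. AluY, SVA_F, LTR5_Hs and the alpha satellite ALR/Alpha did not pass the test, with log2 fold changes of 0.17 ± 0.16, 0.08 ± 0.13, 0.23 ± 0.13 and 0.48 ± 0.21 SE, and SVA_F was -0.030 without sensitive replicate 1. Without sensitive replicate 3 all 4 passed as higher (edgeR adjusted p = 0.0115, 0.0144, 0.00226 and 0.0028, in that order). ALR/Alpha also passed with no filter (edgeR adjusted p = 0.0465) and with the replicate block (0.00871), as did LTR5_Hs with the latter (0.0442).

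Families were then compared with the remaining repeats by camera. LINE-1 subfamilies were called above the other repeats: 123 of 131 L1 subfamilies rose, with a median log2 fold change of 0.64 (camera adjusted p = 1.05e-17, and adjusted p = 0.879 with an estimated correlation). Leaving out 1 library, 68 to 128 of the L1 subfamilies rose. The old L1M group had the smallest adjusted p (85 of 88, median 0.64, camera adjusted p = 6.36e-19, 58 to 86 leaving out 1 library, and adjusted p = 0.879 with an estimated correlation). The other L1P group had the higher median (25 of 30, 8 to 29 leaving out 1 library, median 0.68, adjusted p = 0.905 with an estimated correlation). The 8 young L1 subfamilies, all of which rose (0 to 8 leaving out 1 library), were not set apart from other repeats (median 0.60, camera adjusted p = 0.485). The DNA transposons hAT-Charlie (67 of 75 rose, 29 to 73 leaving out 1 library, median 0.55) and TcMar-Tigger (59 of 64, 13 to 63, median 0.59) were called above the other repeats by camera, with adjusted p = 0.879 for each with an estimated correlation. Alu elements were called below them, with 2 of 51 past the test (0 to 51 leaving out 1 library) and a median of 0.23 (camera adjusted p = 3.01e-10, and adjusted p = 0.879 with an estimated correlation). So were SVA (0 of 6 by edgeR, DESeq2 and limma-voom, 3 with the replicate block, 6 without sensitive replicate 3, 1 at an unadjusted p under 0.05, median 0.23) and ERVK (10 of 42, 0 to 36 leaving out 1 library, median 0.35), each with adjusted p = 0.879 with an estimated correlation. ERV1 (139 of 297, 15 to 268 leaving out 1 library, median 0.45), Satellite (2 of 11, 0 to 7, median 0.34) and centromeric satellites (1 higher and 1 lower of 6, 1 to 2 higher, median 0.10) were called below as well. With an estimated correlation these had adjusted p = 0.923, 0.879 and 0.879. Of 34 families tested, 17 were called, and with an estimated correlation camera called 0, where those 17 had adjusted p = 0.879 to 0.923 (1 family, centr, at an unadjusted p of 0.0328). Without sensitive replicate 3 the calls of SVA, Helitron, TcMar-Tc2, hAT-Blackjack and ERVL were lost (camera adjusted p = 0.278, 0.215, 0.108, 0.119 and 0.219, the last with the direction turned). That of hAT-Blackjack was also lost without sensitive replicates 1 and 2 and resistant replicates 1 and 3 (0.056, 0.0514, 0.0638 and 0.0536), and that of ERVL without resistant replicate 3 (0.0536). With the replicate block hAT-Blackjack (camera adjusted p = 0.0618) and ERVL (0.135) lost their calls. With a filter of 1 CPM in 3 libraries hAT-Blackjack (0.0615) and other L1P (0.0535) lost theirs (camera adjusted p). With the repeat share of each library as a covariate, 51 of 131 L1 subfamilies rose (median 0.33) and 0 of 8 young L1 (median 0.12). The Alu median turned from 0.23 to -0.23, with 0 subfamilies called. This covariate is made from the repeat counts, so it takes up part of their rise.

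**Figure D3:**
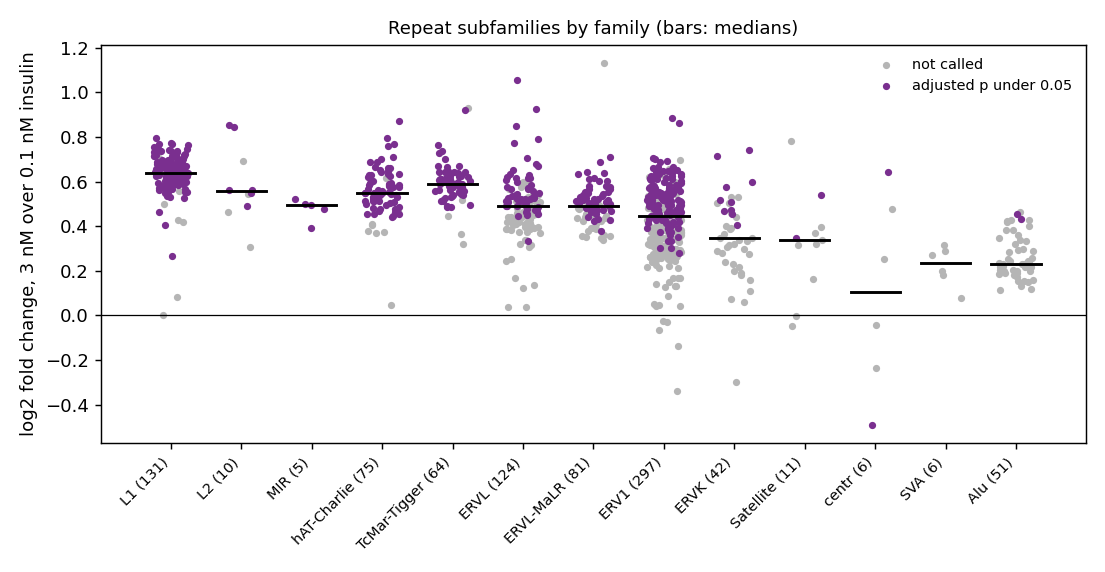
Log2 fold change of 3 nM over 0.1 nM insulin (vertical axis) for each tested repeat subfamily in 13 families, with the number of subfamilies in brackets, purple points for subfamilies past the edgeR test and black bars for medians. L1 lay at a median of 0.64 and Alu at 0.23.

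The share of all counts on repeats was 13.9% ± 3.26 after 0.1 nM insulin and 18.5% ± 1.35 after 3 nM (SD, n = 3 each), a difference of 4.68 points that had the smallest p an exact two-sided permutation test of 3 against 3 allows, p = 0.1 (0.35 after Benjamini-Hochberg adjustment over 7 shares). LINE elements took 5.08% ± 1.12 and 7.58% ± 0.545 (exact p = 0.1). SINE elements took 4.97% ± 1.35 and 6.10% ± 0.521 (exact p = 0.3), LTR elements 2.08% ± 0.468 and 2.68% ± 0.143 (exact p = 0.2) and DNA transposons 1.61% ± 0.296 and 2.02% ± 0.149 (exact p = 0.2). Satellites took 0.0383% and 0.0481% (exact p = 0.3) and retroposons 0.0385% and 0.0431% (exact p = 0.5). The lowest resistant share, 17.6% in replicate 1, lay just above the 17.5% of sensitive replicate 3.

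**Figure D4:**
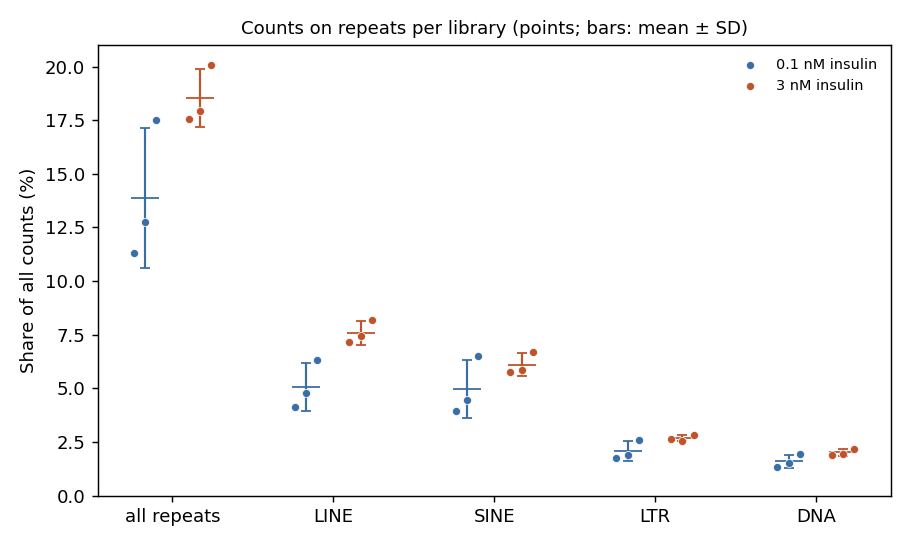
Share of all counts on repeats and on 4 repeat classes (vertical axis, percent) in each library, with points for the 3 libraries of each insulin dose and bars for the mean ± SD. Sensitive replicate 3, at 17.5% for all repeats, sits beside the resistant libraries at 17.6% to 20.1%.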

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

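The GC correction and the repeat share covariate were chosen after the result was seen, and every other setting here was planned. The counts of genes and repeats stayed within 1.5 times the reported ones with DESeq2 (5915 and 873), RLE factors, factors from genes alone, structural RNAs left out, no filter, at least 1 CPM in 3 libraries, limma-voom and the replicate block (7166 and 993). Leaving out 1 library gave 869 to 9025 genes and 189 to 1081 repeats; each such fit has fewer samples, and the cause of the spread was not tested. The highest counts came without sensitive replicate 3 and the lowest without resistant replicate 3. With GC content and length corrected 1631 genes were called, 1314 of them also called before, and with the repeat share as a covariate 556, of which 389 were also called before; the share takes part of the group difference. The share called higher was 29.5% without resistant replicate 1 against 40% in the reported fit. An estimated correlation left 0 lists and 0 families (camera adjusted p = 0.745 for the called lists). The fry test, which asks whether a list moves 1 way without comparing it with other genes, called 2 lists (fibroblast and immune cell markers). It called 17 repeat families, all upward. The families that camera had called below other repeats, such as Alu, SVA, ERVK and ERV1, were not called by fry (fry adjusted p = 0.0876 to 0.629). The replicate numbers are not stated to be pairs, and correlations between libraries of the same number were 0.0996, 0.0744 and 0.195. Those between libraries of different numbers were lower, at -0.157 to 0.0307, so a batch or culture shared by number cannot be excluded. The reported fit ignores such pairs, and the replicate block allows for them.

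Of 141 called genes and repeats named, 78 lost the call without resistant replicate 3, 52 without sensitive replicate 2, 31 without sensitive replicate 1 and 26 without resistant replicate 1. With GC content and length corrected, 61 of 128 kept it. The named calls were not checked with the repeat share as a covariate. Reversals were as follows, and their cause was not tested. With the GC correction the log2 fold changes were 0.11 for RELB, 0.14 for NFKB2, 0.024 for SLC16A3, 0.069 for BOP1, 0.34 for SREBF1, 0.27 for FASN and -0.0285 for NPM1. SREBF1 was also 0.023 with the filter of 1 CPM, and -0.091 to 0.025 over the leave-one-out fits. SRSF2 was -0.016 with no filter, -0.0028 with limma-voom, -0.0030 with the replicate block, and -0.15 to 0.086 leaving out 1 library. Over such fits ITGAM was -0.42 to 0.032, turning without sensitive replicate 3, and SVA_F -0.030 to 0.28, turning without sensitive replicate 1. The immediate early list turned upward with the repeat share as a covariate (camera adjusted p = 0.579), and ERVL turned upward against other repeats without sensitive replicate 3 (0.219; leave-one-out range 0.00905 to 0.219). The difference in repeat share was 3.39 to 6.51 points over the leave-one-out fits and 5.07 with structural RNAs left out. Entries with too few counts for the filter were not tested, which depth limits.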

Other observations

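The comparison of heterochromatic repeat classes, that of intronic genes with their hosts, the GC correction of the intronic difference, the gap between the GC slopes of the groups, the differences of repeat classes and intronic genes per library, and the tests of the GC trend and repeat share on the FOXO and stress lists were chosen after the result was seen. Classes of genes moved apart. Among 14849 protein-coding genes 1103 rose and 2586 fell, among 6218 long noncoding RNAs 476 rose and 299 fell, and among 3454 processed pseudogenes 169 rose and 37 fell, by edgeR at an adjusted p under 0.05. Medians differed by position within the noncoding classes. Long noncoding RNAs wholly inside introns of coding genes had a median log2 fold change of 0.29 (1221 genes) against 0.08 for intergenic ones (1799), and processed pseudogenes had 0.28 (1767) against 0.00 (1495). Where an intronic noncoding gene had a tested host on its strand (1316 genes), the hosts had a median of -0.02, and 79% of the intronic genes lay above their host.

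Repeat subfamilies rose in the resistant libraries. Over repeats the median log2 difference was 0.59 for sensitive replicate 3 minus sensitive replicate 1. It was 0.19 for the resistant mean minus sensitive replicate 3. No prediction was set for this comparison, and variation between libraries at 1 insulin dose cannot be told apart from the dose as a source of the rise. Genomic DNA would have added 15.2 CPM to the 410 olfactory receptor genes, but their mean differed by -0.0705 CPM, resistant minus sensitive (7.60 ± 0.392 and 7.53 ± 0.715, SD, n = 3; the highest resistant minus the lowest sensitive library was 0.845), which argues against it. Whether release of heterochromatic classes was the whole cause cannot be decided, because the comparison was chosen after the result was seen and its classes differed in direction. The median of the 76 satellite, ERVK, SVA and young L1 subfamilies lay -0.18 from that of the 15 L2 and MIR subfamilies. Satellites (0.32), ERVK (0.35) and SVA (0.23) lay below the L2 and MIR median of 0.52, and young L1 (0.60) lay above it. Subfamilies are not independent replicates, but per library the gap of 0.117 between the groups was wider than the range within a group (0.0694). More intronic RNA in the resistant libraries met its prediction over genes, which are not independent replicates: intronic noncoding genes lay 0.24 above intergenic ones (0.16 to 0.36 leaving out 1 library, 0.19 with GC content and length corrected), but per library the gap between the groups was 0.00565 against a range of 0.324. How much of the rise in repeats it carries was not measured, and whether insulin altered splicing, nuclear RNA or its yield stays open, since no library measured these apart.

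GC-rich genes were lower in the resistant libraries. Across 14849 protein-coding genes, which are not independent replicates, the log2 fold change correlated with GC content at Pearson's r = -0.484 and Spearman's rho = -0.568. Relative to the mean of the 6 libraries, the slope per 10 points of GC content was 0.14, 0.09 and 0.08 in the sensitive and -0.09, -0.10 and -0.11 in the resistant libraries. The range among sensitive libraries was 0.30 of the difference between groups and that among resistant libraries 0.0792, and since the first lies between the bounds set before the test, some part of variation between libraries at 1 dose cannot be told apart from the rest. Variation of the size seen within these groups is argued against as the whole cause. The gap of 0.173 between the groups' slopes was 2.86 times the wider range within a group (0.0606). That comparison was chosen after the result was seen, and the labels do not say whether the replicates were separate cultures. Larger variation between cultures at 1 dose therefore stays open. An effect of the insulin dose and a difference in library preparation stay open too, because the labels give no batch.

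Camera called FOXO targets lower (7 of 20 fell and 1 rose) and integrated stress response genes higher (5 of 17 rose and 2 fell) in the resistant libraries, each with adjusted p = 0.745 with an estimated correlation. With a GC content and length trend removed, both lists were still called at the preset correlation (the larger camera adjusted p = 2.16e-05, medians -0.23 and 0.27). With an estimated correlation the camera adjusted p was 0.684 and 0.511. At the preset correlation camera called up to 24 lists in splits that mixed the groups. Such calls therefore cannot decide whether the trend was the whole cause. With the repeat share as a covariate the stress genes were called (camera adjusted p = 0.000242, median 0.05 before and 0.23 after). With an estimated correlation their camera adjusted p was 0.538, so whether that share was their whole cause cannot be decided either. FOXO targets were not called with this covariate (camera adjusted p = 0.386), as their median went from -0.24 to -0.04 (SD over 20 genes 0.39 and 0.34). For both lists the share cannot be told apart from insulin, because 56.9% of its variance lies between the groups. An effect of the insulin dose stays open for both lists. The stress genes' call rested on sensitive replicate 3 (camera adjusted p = 0.248 without it) and on resistant replicate 1 (0.0684).

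The 6 libraries can be split into 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 5152 genes and 711 repeats, in each case only itself among the 10 with as many (1 split), and the highest of the other splits gave 0 and 0. Every other split mixes the groups, so a group difference of any origin widens the spread within its sides and lowers the calls. These 0 calls therefore cannot tell an insulin effect from a batch or from chance. For gene lists the real split gave 15 and the highest other 24, and 3 splits, the real one included, gave as many. For repeat families it gave 17, the highest other 17, and 3 splits gave as many, again with the real one included.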
